A study of Mus musculus with 2 samples.

How the data were processed

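RNA sequencing was done on cultured mouse bone marrow progenitors with loxP-flanked Cebpa and CreER, transduced with tagged Hoxa9 and Meis1, after 72 h of ethanol or 5 nM 4OHT. Per the labels' protocols, total RNA was purified on columns with DNase treatment and made into libraries with an Illumina TruSeq RNA kit; whether the libraries kept strand is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.0.0.7, Cuffdiff 2.0.2 and the genome build mm9, with no role for each, and the gene annotation is not given in the sources used here. The series' design text describes biological replicates, and each of the 2 samples joins 2 of them.

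The authors deposited 1 table with 23309 rows and, per the file headers, 1 FPKM value per gene and condition. FPKM, fragments scaled by transcript length and sequencing depth, is the authors' own unit here, and the scaling they applied between conditions is not given. The authors' deposited table also gives a test statistic, a score whose range is not fixed, a p-value and a q-value per row, a linear fold ratio, and a status. Status was OK for 11953 rows, not tested for 11198, too little data for 156 and failed for 2. The deposited q-value equals a Benjamini-Hochberg adjustment over the rows with status OK, to within 5.28e-07. The deposited p-values are whole multiples of 5e-05, and 363 tested rows share the smallest, whose q is 0.00165 in the authors' deposited table. The deposited p follows the deposited score by the normal law in 41.7% of tested rows, within 0.05 log10 units, where 95% had been set as the least share. For that reason no standard error was taken from the score, and fold changes are given with q alone. Steps of one size are what a p-value from resampling would show, as in later Cuffdiff releases, so it is in doubt that the release named in the notes made these p-values. Which test lies behind each printed q is therefore not known. The deposited log2 column was not used, since spreadsheet errors fill part of it, and log2 ratios were computed from the FPKM values. In 27 rows the gene symbol had been turned into a date, 1 of them called, and 103 rows join several symbols. All 6829 rows at 0 in both conditions stayed out of the tests. Coordinates are those of the deposited loci on mm9, with starts written from 1. A locus can span several overlapping genes. The reference annotation at hand is of another build and gave no coordinate.

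Groups were taken from the labels, vehicle and 4OHT, with 1 sample each, and no other column of sample values was present. With 1 value per condition, no test was run here. A gene was called higher or lower when the authors' deposited table gave status OK and a q under 0.05, and the words rose and fell are used for such genes. The columns have the form of Cuffdiff output, per the file headers, and the submitters' processing notes name Cuffdiff without saying that it made these calls. No read count is held in the table, so depth is unknown and no interval for counting error is given. The size of change that was called serves as a guide to precision. Rows were binned by their level in the higher condition. Rows with at least a 2-fold change and a value above 0 in both conditions were counted, with small RNAs left out. Of these, 98% were called between 20 and 100 FPKM (49 of 50) and 100% above that (8 of 8), against 36.4% below 1 FPKM (64 of 176). The smallest log2 change called was 0.77 below 1 FPKM and 0.47 between 20 and 100 FPKM. None of 154 tested microRNA, snoRNA and scaRNA rows was called.

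Genes were grouped by 23 lists of 336 entries, fixed before the data were examined, as were the threshold, the alternatives and the rule for naming genes. The lists cover the C/EBP family, genes tied to Hoxa9 and Meis1, CDK inhibitors, cell cycle, blood lineages that lineage-depleted marrow can yield, receptors, transcription factors, cytokines, and controls for p53, interferon, cholesterol synthesis, housekeeping and sex. Of the entries 327 matched a row by symbol, 5 by an older symbol and 4 through a joined row. A member counted as measured at 1 FPKM or more in the higher condition. A list was described by its called members, by the number called when the deposited p of its members was adjusted over the list alone, and by its median log2((4OHT FPKM + 1)/(vehicle FPKM + 1)). That ratio, with a pseudocount of 1, understates the change of low genes. The median was placed as a percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. The percentile describes these samples and is not a p-value, and lists outside 2.5 to 97.5 were counted as standing apart. Named genes were 5 set in advance (Cebpa, Hoxa9, Meis1, Cdkn2a and Cdkn2b), the 8 largest rises and 8 largest falls among called genes of at least 1 FPKM with a single symbol that is not a predicted gene or small RNA, and from each list the 2 called members with the largest ratio. List members that were not called were named to show it. Further called list members were named after their values were seen, as were the Gimap and Gbp genes and the genes that open the other observations.

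Alternatives covered a stricter q, a minimum log2 ratio of 1 in size, minimum levels of 1 and 5 FPKM, pseudocounts of 0.1 and 5, centring on the median of measured genes, and duplicate symbols. Centring had little to shift, since the median log2 ratio of measured genes was 0.000310. Neighbouring genes were compared with calls shuffled 10000 times among genes of like expression. The steps were tested on simulated data. The random list step placed 5% of 200 simulated lists of 13 genes outside its bounds with no shift. With a log2 shift of 0.25 it placed 99.5% outside, on 10989 genes, for the comparison of vehicle with 4OHT. Members were drawn at random and values were shuffled in that simulation. Its 5% therefore does not extend to lists whose members vary together between cultures. The shuffle exceeded its upper bound in 5% of 40 simulations without planted neighbours and in 100% with 25 planted, on 10932 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.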

Results

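Gene expression was measured by RNA sequencing in mouse bone marrow progenitors whose Cebpa gene could be removed at will. Cebpa encodes C/EBPα, a transcription factor required for granulocyte and monocyte development. The cells came from lineage-depleted marrow of mice that carried loxP-flanked Cebpa alleles and CreER, a Cre recombinase that enters the nucleus once it binds 4-hydroxytamoxifen (4OHT). They were transformed with retroviruses for tagged Hoxa9 and Meis1, a pair of homeodomain proteins that drive acute leukaemia together, and grown with interleukin-3. Cells received ethanol, the vehicle, or 5 nM 4OHT for 72 h. There was 1 deposited sample per condition, and each joined 2 replicates, so every gene has 1 value per condition, in FPKM (fragment counts scaled by transcript length and sequencing depth), and no spread between replicates can be given. Of 23309 rows, 11953 were tested by the authors and 10989 reached at least 1 FPKM in the higher condition. The values summed to 684536 FPKM in vehicle cells and 673516 FPKM after 4OHT, and 10796 and 10816 rows reached 1 FPKM. The table holds no read counts, so the depth behind each value is unknown.

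The first question was how far 4OHT lowered Cebpa itself and whether the transforming genes stayed at their level. Cebpa fell from 109 to 42.8 FPKM, which left 39.2% of the vehicle level, with q = 0.00165 in the authors' deposited table. The gene lies on chromosome 7 of mm9 at positions 35904312 to 35906951, and which part of it the loxP sites flank is not given in the sources used here. Hoxa9 stood at 1010.1 FPKM in vehicle cells and 868 FPKM after 4OHT, and Meis1 at 162 and 155 FPKM, with q of 0.901 and 1.00 in the authors' deposited table. Those rows do not separate transcripts of the transduced copies from those of the resident genes. Among the 6 measured C/EBP family members, Cebpa fell, Cebpg rose from 28.3 to 41.8 FPKM, and 4 did not pass the test. Cebpb had 30.4 and 21.5 FPKM and Cebpe, which acts late in granulocyte development, 17.1 and 13.6 FPKM. Adjusted over the list alone, 1 member was higher and 2 were lower. The family's median log2 ratio was -0.34, at percentile 0.04 of 10000 random lists matched on expression.

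The main comparison asked which transcripts differed between 4OHT and vehicle in these transformed cells. By itself it cannot separate loss of Cebpa from other effects of 4OHT or of Cre activity. After 4OHT, 5 of 8 measured late neutrophil genes and 7 of 15 monocyte genes fell and none rose, and 9 of 13 stem and early progenitor genes rose and none fell. Of 9 primary granule genes 4 fell and 1 rose, and of 11 mast cell and basophil genes 4 rose, 2 of which, Kit and Gata2, are also stem cell genes. In all, 335 rows were higher and 372 were lower at q under 0.05 in the authors' deposited table, 5.91% of those tested. Changes of at least 2-fold were more frequent among the falls, with 192 rows against 136 rises. Across the measured genes the conditions had a Pearson r of 0.972 on the log2(FPKM + 1) scale, a description across genes, which are not independent replicates.

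**Figure D1:**
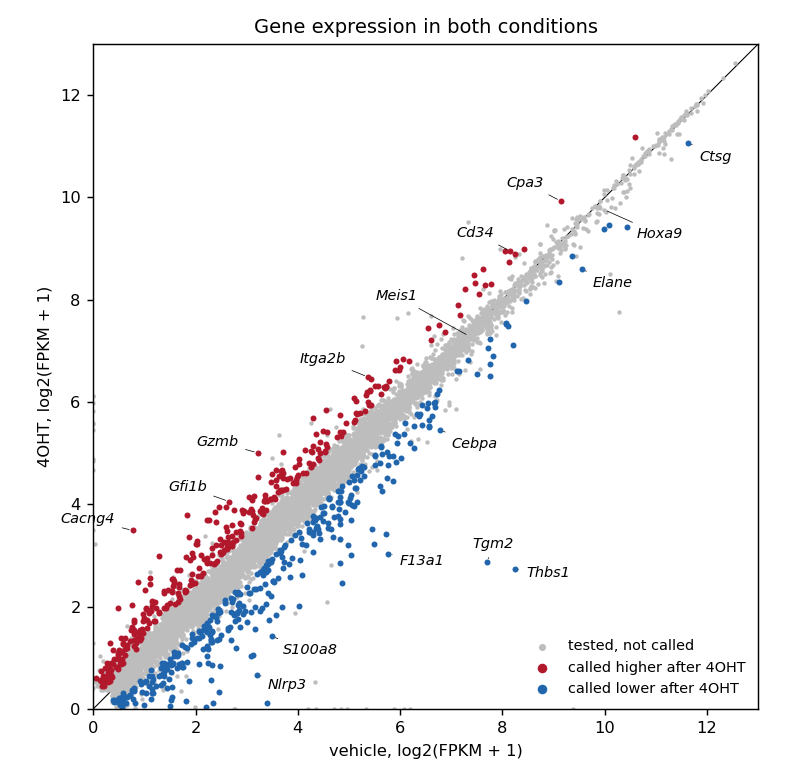
Each point is a tested gene, with its vehicle value on the x axis and its 4OHT value on the y axis, both as log2(FPKM + 1). The line marks equal values; the 335 genes called higher are red, the 372 called lower are blue, and of the called genes Thbs1 and Tgm2 lie farthest below the line.

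Among called genes, the largest falls on the log2(FPKM + 1) scale, by which genes were ranked, exceeded that of Cebpa itself. Thbs1, which encodes the matrix protein thrombospondin-1, fell 53.8-fold, from 303 to 5.62 FPKM (mm9 chromosome 2, 117937658 to 117952869). Tgm2, a transglutaminase that crosslinks proteins, fell 32.8-fold, from 207 to 6.31 FPKM (chromosome 2, 157942141 to 157972128). F13a1, the catalytic subunit of coagulation factor XIII, fell from 53.6 to 7.17 FPKM. Nlrp3, the sensor of an inflammasome, fell from 8.21 to 0.585 FPKM. Lipg, a secreted lipase, fell from 28.0 to 4.53 FPKM, and Aldh1a3, an enzyme of retinoic acid synthesis, from 52.1 to 9.66 FPKM. Tmem86a fell from 44.2 to 8.29 FPKM, and the tight junction gene Cldn11 from 9.49 to 0.0879 FPKM. In the authors' deposited table, q was 0.00806 for Cldn11 and 0.00165, the smallest q it holds, for the other 7.

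The rises were led by Cacng4 on the log2(FPKM + 1) scale. Cacng4, a calcium channel gamma subunit gene, rose 14.5-fold, from 0.705 to 10.2 FPKM (mm9 chromosome 11, 107596094 to 107655778). Gzmb, a serine protease of cytotoxic granules, rose from 8.28 to 31.1 FPKM, and Lat, a signalling adaptor of T cells and mast cells, from 4.18 to 13.4 FPKM. Cd74, the invariant chain of MHC class II, rose from 0.826 to 4.60 FPKM, and the chemokine Ccl5 from 0.397 to 2.94 FPKM. Pglyrp2, an amidase that cleaves peptidoglycan, rose from 1.45 to 6.91 FPKM, Gimap5, a GTPase of lymphocytes, from 4.47 to 14.4 FPKM, and Fam20a from 2.66 to 9.25 FPKM. In the authors' deposited table, q was 0.0472 for Ccl5 and 0.00165 for the other 7.

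Measured genes of mature neutrophils and monocytes went down as groups. Of 17 listed genes of secondary and tertiary granules and late neutrophils, 8 were measured. Among those 8, 5 fell and none rose, with a median log2 ratio of -0.52. The unmeasured genes, below 1 FPKM in both conditions, included Ltf (0.0751 and 0.0630 FPKM), Ngp (0.673 and 0.676 FPKM), Camp, Mmp9, Fcnb and Retnlg. The falls therefore cover only part of that list. S100a8 fell from 10.2 to 1.67 FPKM, its partner S100a9 from 8.86 to 2.92 FPKM, and Lcn2, the iron-binding lipocalin, from 57.2 to 21.0 FPKM. Cybb, the phagocyte oxidase subunit, and the chemokine receptor Cxcr2 fell too, and Padi4, Pglyrp1 and Mmp8 did not pass the test. Of 15 measured monocyte and macrophage genes, 7 fell and none rose, with a median of -0.37. They were F13a1, Lgals3 (48.8 to 18.2 FPKM), the integrin Itgam (33.1 to 14.5 FPKM), Cd14 (16.9 to 8.26 FPKM), Ly6c2 (551 to 323 FPKM), Cd68 and the transcription factor Irf8. Csf1r, the receptor for macrophage colony-stimulating factor, had 2.84 and 2.55 FPKM and did not pass the test. Mrc1, below 1 FPKM and outside the measured set, rose from 0.185 to 0.499 FPKM. Adjusted over the list alone, 5 late neutrophil genes were lower, and 8 monocyte genes were lower and 1 higher.

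Primary granule genes, which mark promyelocytes, were split. Of 9 measured members, 4 fell, 1 rose and 4 did not pass the test, and adjusted over the list alone 5 were lower and 1 higher. Elane, neutrophil elastase, fell from 752 to 385 FPKM, Prtn3, proteinase 3, from 1087 to 707 FPKM, Ctsg, cathepsin G, from 3175 to 2146 FPKM, and Ms4a3 from 658 to 461 FPKM. Serpinb1a, an inhibitor of those proteases, rose from 218 to 315 FPKM. Mpo, the myeloperoxidase gene, had 496 FPKM in vehicle cells and 603 FPKM after 4OHT, and Lyz2 99.0 and 104 FPKM, and neither passed the test. The median log2 ratio was -0.42. For this list, the late neutrophil list and the monocyte list, the median lay at percentile 0 of the matched random lists, and 0% of those lists held as many genes called lower.

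Stem and early progenitor genes rose together. Of 13 measured members, 9 rose and none fell, against a mean of 0.315 in matched random lists, and adjusted over the list alone 10 were higher. The median log2 ratio was 0.68, at percentile 100. Cd34 rose from 284 to 493 FPKM, Kit, the stem cell factor receptor, from 20.1 to 32.8 FPKM, Erg from 41.3 to 73.2 FPKM and Angpt1 from 33.95 to 64.2 FPKM. Mycn rose from 5.77 to 13.8 FPKM and Procr, a surface marker of stem cells, from 0.741 to 2.25 FPKM. Gata2, Cd48 and Hlf were the other members that rose. Tal1 had 29.4 and 40.6 FPKM, with q = 0.0624 in the authors' deposited table, and Ly6a, Lmo2 and Meis1 did not pass the test either.

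Several genes tied to Hoxa9 and Meis1 in leukaemia overlapped with that group. Of 18 measured members, 5 rose, 1 fell and 12 did not pass the test, and adjusted over the list alone 6 were higher and 1 lower. The risers were Flt3, a receptor tyrosine kinase (10.3 to 23.1 FPKM), Sox4 (39.2 to 69.3 FPKM), Erg, Cd34 and Hlf, of which Erg, Cd34 and Hlf are on both lists. Cd28 fell from 2.39 to 0.770 FPKM. Myb, with 152 and 149 FPKM, and Myc, with 209 and 190 FPKM, did not pass the test. The list median of 0.04 lay at percentile 92.5, inside the central 95% of random lists. Hoxa10 and Mecom were listed at 0, as was Hmgcs1, an enzyme that every cell uses, so those entries give no level.

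Markers of the mast cell and basophil lineage rose in part. Of 18 listed members 11 were measured, and of these 4 rose and none fell. The same number were higher adjusted over the list alone. Mcpt1, Mcpt2 and Mcpt4 were listed at 0 in both conditions. The median of 0.30 lay at percentile 100. Cpa3, mast cell carboxypeptidase, rose from 562 to 975 FPKM, Slc18a2, a vesicular amine transporter, from 21.5 to 42.1 FPKM, and Kit and Gata2 (58.4 to 97.7 FPKM), both shared with the stem cell list, were the others. Mcpt8, the basophil protease, had 61.2 and 61.0 FPKM. The eosinophil list had 1 of 5 measured members higher, the lectin row Siglec5, an older symbol of Siglecf, which rose from 6.49 to 13.9 FPKM. Its median was 0.41, at percentile 99.7, and adjusted over the list alone 3 members were higher.

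Erythroid and megakaryocyte genes had few called members. Of 5 measured erythroid rows, 1 rose, the joined row of the beta globin genes Hbb-b1 and Hbb-b2 (175 to 321 FPKM), and reads of such near-identical copies cannot be assigned with certainty. Gata1 had 0.609 and 1.23 FPKM, with q = 0.0698 in the authors' deposited table. The median was 0.47, at percentile 100, and adjusted over the list alone 3 rows were higher. Of 7 measured megakaryocyte and platelet genes, 2 rose, Itga2b, the alpha chain of the platelet fibrinogen receptor (40.3 to 88.8 FPKM), and Gp5 (0.962 to 2.62 FPKM). Pf4, platelet factor 4, had 10.97 and 10.49 FPKM. That list's median was 0.27, at percentile 99.7, and adjusted over the list alone 3 members were higher.

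Lymphoid and dendritic cell markers were mostly too low to measure. In the T and NK cell list 3 of 14 members were measured and 1 rose, Nkg7, a protein of cytotoxic granules (33.2 to 66.1 FPKM), the same count as adjusted over the list alone. Its median was 0.04, at percentile 71.5. In the B cell list 1 of 12 members was measured, Ebf1, which rose from 0.754 to 1.54 FPKM, and no percentile was taken. Of 5 measured dendritic cell and MHC class II genes, 2 rose, Cd74 and H2-Aa (0.535 to 1.602 FPKM), and 1 fell, H2-Ab1 (44.6 to 29.8 FPKM), counts that were the same adjusted over the list alone. H2-Eb1, below 1 FPKM, rose from 0.214 to 0.735 FPKM. The median of 0.12 lay at percentile 91.7.

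Among myeloid transcription factors, 2 of 16 measured members rose and 1 fell. Gfi1b, a transcriptional repressor active in erythroid and megakaryocyte cells, rose from 5.31 to 15.6 FPKM, Gata2 rose, and Irf8 fell from 21.7 to 14.7 FPKM. Gfi1 had 72.9 and 53.1 FPKM, with q = 0.0531 in the authors' deposited table, and Spi1, the gene of PU.1, 99.8 and 81.3 FPKM, with q = 0.491 there. Adjusted over the list alone, 4 were higher and 3 lower, and the median of 0.12 lay at percentile 99.7. Of 14 measured growth factor receptors, Flt3, Kit and the interleukin-33 receptor Il1rl1 (9.12 to 15.8 FPKM) rose, and Tnfrsf1b (33.7 to 18.9 FPKM) and Ifngr1 (104 to 70.6 FPKM) fell. Adjusted over the list alone, 3 receptors were higher and 4 lower, and the median was -0.14, at percentile 0.31. Of 10 measured cytokine and chemokine genes, Il6 rose from 5.13 to 10.1 FPKM and Il1rn, the interleukin-1 receptor antagonist, fell from 5.95 to 1.29 FPKM, with 2 higher and 3 lower adjusted over the list alone. That median was -0.03, at percentile 27.3, and Ptgs2, below 1 FPKM, fell from 0.637 to 0.212 FPKM.

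A further question was whether cell cycle inhibitors changed after 4OHT. Of 6 measured CDK inhibitor genes, Cdkn2b, the gene of p15, rose from 7.70 to 12.8 FPKM, with q = 0.0158 in the authors' deposited table. Its neighbour Cdkn2a, which encodes p16 and p19Arf, had 20.01 FPKM in vehicle cells and 28.8 FPKM after 4OHT, and q = 0.118 there. They lie on chromosome 4 of mm9, Cdkn2a at 88920377 to 88940523 and Cdkn2b at 88952198 to 88956941. Adjusted over the list alone, 2 inhibitors were higher, and the median of 0.13 lay at percentile 95.2. None of the 25 measured cell cycle genes passed the test over all genes or adjusted over the list alone, and their median was -0.09, at percentile 1.25. Rrm2, a ribonucleotide reductase subunit, had 128 and 92.4 FPKM, with q = 0.0601 in the authors' deposited table, and Pcna 399 and 389 FPKM.

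Lists that 4OHT or Cre activity alone might move were measured for comparison. Of 13 measured p53 target genes, Trp53inp1 (2.20 to 4.45 FPKM) and Bbc3 (8.86 to 14.2 FPKM) rose and Pmaip1 (27.1 to 14.1 FPKM) fell, with 3 higher and 1 lower adjusted over the list alone. Cdkn1a had 43.3 and 52.3 FPKM and Mdm2 27.0 and 27.1 FPKM, and the list median of 0.08 lay at percentile 94.2. Of 16 measured cholesterol synthesis genes, Sc5d fell from 38.3 to 22.5 FPKM, 1 was lower adjusted over the list alone, and the median was -0.14, at percentile 0.2. None of 8 measured interferon response genes passed the test on either adjustment, with a median of 0.10 at percentile 82.3, while Rsad2, below 1 FPKM, fell from 0.417 to 0.164 FPKM. The 13 housekeeping genes and the 5 sex-linked genes held no called member on either adjustment, with medians of -0.04 and 0.08 at percentiles 30.0 and 82.4. Xist had 4.23 and 4.75 FPKM and the Y-linked Eif2s3y 44.8 and 45.1 FPKM. Of the 22 lists with a percentile, 6 lay above the central 95% of matched random lists and 7 below it.

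**Figure D2:**
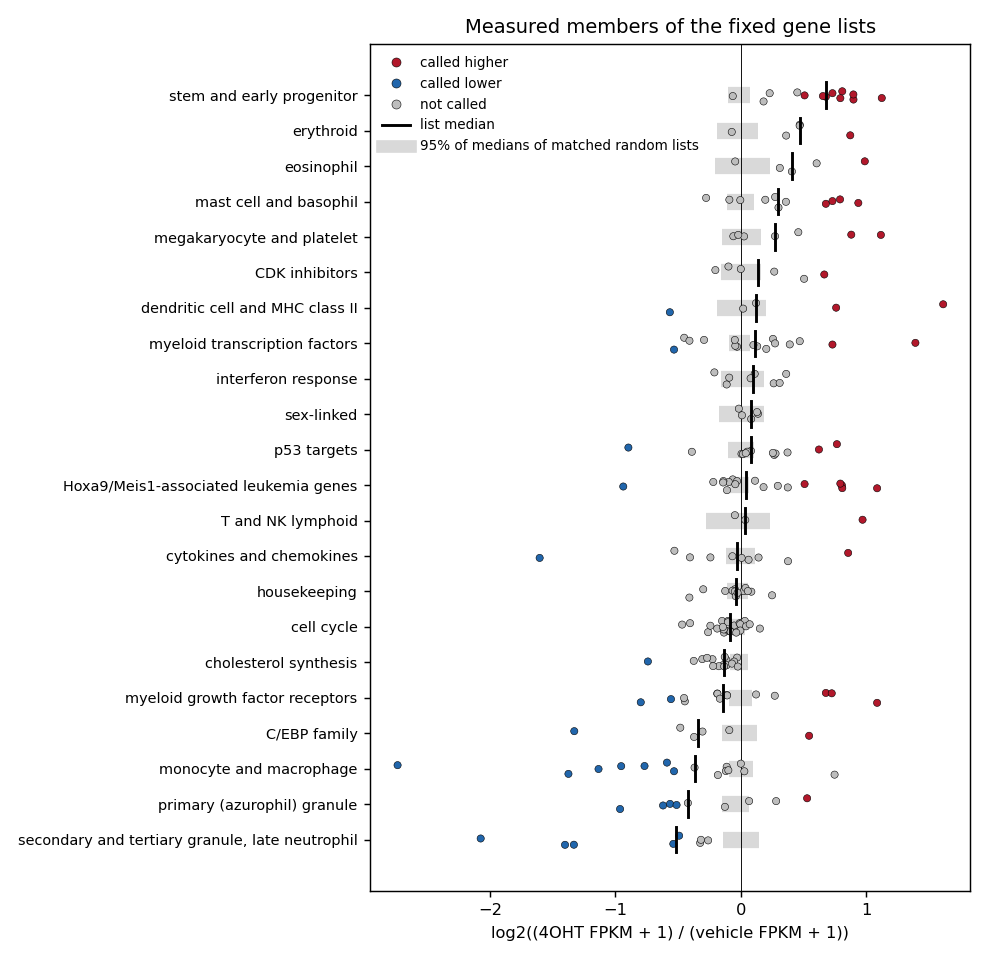
Each row is a gene list and each point a measured member, with its log2((4OHT FPKM + 1)/(vehicle FPKM + 1)) on the x axis; red points were called higher, blue lower and grey neither. Black bars are list medians and grey bands hold 95% of the medians of matched random lists; the stem and early progenitor median, 0.68, is the highest and the late neutrophil median, -0.52, the lowest.

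Neighbouring members of a pair of gene families moved together, and both were chosen after their values were seen. The Gimap genes, GTPases of lymphocytes, form a cluster on chromosome 6 of mm9 between 48597233 and 48720850. Of its 8 rows 6 rose, among them Gimap1 from 19.4 to 40.7 FPKM and Gimap6 from 11.3 to 22.4 FPKM, and Gimap7 and Gimap3 did not pass the test. The Gbp genes, interferon-inducible guanylate-binding proteins, form clusters on chromosomes 5 and 3. On chromosome 5 (105443172 to 105775491) Gbp8 fell from 4.08 to 0.0764 FPKM, Gbp9 from 1.82 to 0.0420 FPKM and Gbp4 from 3.61 to 0.0249 FPKM. In the authors' deposited table their q was 0.00310, 0.00806 and 0.0235. Gbp6, with 2.98 FPKM in vehicle cells and 0.0188 FPKM after 4OHT, had q = 0.135 there. The 6 rows of that cluster summed to 13.4 FPKM in vehicle cells and 0.178 FPKM after 4OHT, 75.2-fold lower. The 5 rows on chromosome 3 held no called gene and summed to 27.0 and 23.9 FPKM. Members of either family share sequence, and how reads that match several copies were assigned is not given in the sources used here.

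**Figure D3:**
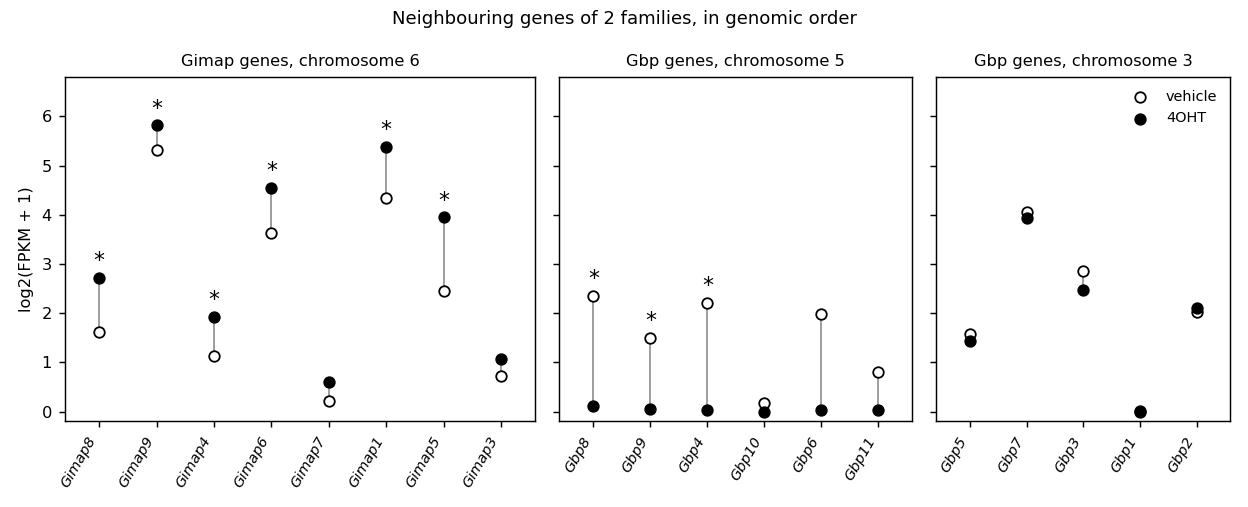
Open circles give vehicle values and filled circles 4OHT values as log2(FPKM + 1), for the Gimap genes of chromosome 6 and the Gbp genes of chromosomes 5 and 3 in genomic order. A star marks a gene called at q under 0.05: 6 Gimap genes are higher after 4OHT, and 3 Gbp genes of chromosome 5 are lower and close to 0.

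The precision of these calls depended on expression. Of rows with a change of at least 2-fold, 36.4% were called where the higher condition was below 1 FPKM, 78.7% between 1 and 5 FPKM, and 91.8% between 5 and 20 FPKM, so a low gene that missed the test may have changed without being detectable.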

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

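The authors' own mark for a 1.5-fold change was the alternative chosen only after the result was seen. The fall of Cebpa kept its direction, with log2 ratios from -1.35 to -1.25 over the pseudocounts and scalings tried. Genes higher after 4OHT numbered 205 at q under 0.01, 136 with a log2 ratio of at least 1, and 196 among genes of at least 5 FPKM, against 335, and genes lower numbered 192 with that ratio and 227 at that level, against 372. The stricter q and the added ratio cutoff can only lower a count, by their construction. The setting of at least 5 FPKM drops rows but adjusts p again over the rest, so its count could move either way. The remaining counts lay between 291 and 335 for rises and between 254 and 372 for falls, where 254 is the count at q under 0.01. List members called lower, summed over the lists, numbered 16 at q under 0.01, against 25. With members of at least 5 FPKM, the percentile of the Hoxa9 and Meis1 list came to 100 and that of the CDK inhibitors to 99.96, past the upper bound, and the megakaryocyte list to 94.76, inside it. With a pseudocount of 5, the CDK inhibitors reached 98.53 and the p53 targets 98.34, past the bound. With all members above 0, the erythroid list came to 90.58 and the myeloid transcription factors to 96.45, both inside the bounds, and the cytokine list to 0.25, outside them. That setting also took the CDK inhibitors to 46.2 and the Hoxa9 and Meis1 list to 48.4, from above to below the middle of the random lists. The cause of those list shifts was not tested, and 99 list percentiles, those 2 included, stayed on their side of the bounds. Counts of called members in single lists moved by over 1.5 times in 6 instances for rises and 5 for falls. At q under 0.01, primary granule genes called lower went from 4 to 2 and those called higher from 1 to 0. Late neutrophil genes called lower went from 5 to 3. Of the 16 genes named for the size of their change, 8 were the same with a pseudocount of 0.1 and 9 with 5. At q under 0.01, 7 of the 46 called genes named by the rules set in advance were lost, Cdkn2b, Cebpg, Ccl5, the joined Hbb row, Ebf1, H2-Aa and Rsad2. Called genes named after their values were seen are outside that count, and some of them, such as Ctsg and Irf8, were lost too. No paired analysis was possible because the table has 1 column per condition, and for the same reason limma, a fit with a replicate block and leaving out each replicate were not run. Depth is unknown, and calls were least complete below 1 FPKM.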

Other observations

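The tests of the interferon response list, and of p53 targets and cholesterol synthesis against 4OHT or Cre activity, were chosen only after the result was seen. Further genes, also picked after their values were seen, changed outside the lists. Among regulators, Id3, an inhibitor of bHLH factors, rose from 2.71 to 6.51 FPKM, Zbtb16, the gene of PLZF, from 2.18 to 4.24 FPKM, and Hmga2, a chromatin protein of fetal stem cells, from 0.754 to 1.84 FPKM. Hif1a, the oxygen-regulated transcription factor, fell from 76.5 to 45.2 FPKM and the homeobox gene Hopx from 15.9 to 5.09 FPKM. The DNA methyltransferase Dnmt3b rose from 6.35 to 9.38 FPKM and its cofactor gene Dnmt3l fell from 7.45 to 2.69 FPKM. Among cell surface and signalling genes, the interleukin-4 receptor Il4ra fell from 53.6 to 26.1 FPKM, Il2ra from 23.2 to 11.4 FPKM, the endotoxin receptor Tlr4 from 21.4 to 11.8 FPKM and Cd33 from 24.2 to 10.5 FPKM. The cytokine Csf1 fell from 8.52 to 2.79 FPKM and Socs3 from 19.5 to 10.6 FPKM, while Socs2 rose from 41.2 to 60.5 FPKM and Pdgfrb, a growth factor receptor gene, from 6.62 to 13.3 FPKM. Haptoglobin, Hp, fell from 27.2 to 8.94 FPKM and complement C3 from 18.7 to 7.33 FPKM.

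Of 306 symbol families with at least 5 measured members, 11 had at least 3 members called the same way. Of those 11, Gimap had the largest share, with 6 of 7 measured members higher. Of 5 measured carbohydrate sulfotransferases, Chst11 (19.3 to 11.9 FPKM), Chst13 (3.57 to 1.90 FPKM) and Chst15 (4.36 to 2.28 FPKM) fell. Families were formed from the start of the symbol alone, and no test allowed for their choice among the 306.

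Gbp8, Gbp9 and Gbp4 of the chromosome 5 cluster fell to near 0 together, and reads moving between near-identical copies could give such a fall. The summed FPKM of the 11 Gbp rows fell by 0.74 on the log2 scale and no Gbp row was called higher. The chromosome 3 copies changed by -0.17 where 0.57 was needed if they had gained what was lost in equal FPKM. These values argue against a shift of reads among the 11 rows. Reads left out or assigned to other rows were not tested. The 10 measured genes within 1 Mb had a median log2 ratio of -0.21, from -0.75 to 0.12, with 1 called, Spp1. A fall like that of the cluster therefore did not reach them. None of them lies between 104983230 and 105443172 or between 105775491 and 105844794, so a wider loss that ended in those gaps is not excluded. A lower interferon response stays open: the interferon list had a median of 0.10, but 6 of its 8 measured members lay below 5 FPKM, Rsad2, called lower, was not among them, and the interferon-gamma receptor gene Ifngr1 fell, while a difference between the cultures in descent from cells with unlike Gbp alleles was not tested. Silencing or deletion restricted to that cluster and the gaps beside it after 4OHT is a hypothesis. The design offers Cebpa loss as its possible biological source, untested. Cebpa RNA kept 39.2% of its vehicle level, whereas the sum of the cluster fell 75.2-fold. The share of cells that lost Cebpa was not measured here.

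Neighbouring genes were called in the same direction more often than shuffled calls. There were 53 such pairs among 10769 genes, against a mean of 18.8 and a highest value of 37 in 10000 shuffles within expression bins, so the tendency of expressed genes to lie together is excluded as the whole cause. Without overlapping pairs or pairs with a like symbol start 39 remained, against 25 at the upper bound of the shuffles. Overlap and a like symbol start are therefore not the whole cause. Related genes with unlike symbols, or with short ones such as F7 and F10, were not recognised as related, so shared reads are not excluded. Runs of 3 or more were the Gimap genes, the Gbp genes, Gm7694, Nos1ap and Olfml2b on chromosome 1, and a stretch of chromosome 8 where Mcf2l, F7 and F10, and then Lamp1, Grtp1 and Adprhl1, fell; F7 went from 27.4 to 15.6 FPKM and F10 from 27.1 to 15.4 FPKM. Regulatory elements shared by neighbours are a hypothesis that no test here addressed.

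The genes that changed might respond to 4OHT or to Cre activity and not to the loss of Cebpa. The p53 target median lay at percentile 94.2, inside the bounds, and at 98.34, above them, with a pseudocount of 5, with Bbc3 and Trp53inp1 higher and Pmaip1 lower. The cholesterol synthesis median was -0.14, a shift toward lower and not higher expression after 4OHT. That median stood apart below the bounds, at percentile 0.2, and between 0.16 and 0.21 under the alternatives. These sources cannot be told apart, because every 4OHT-treated cell also carried the loxP-flanked gene, and cells without it that received 4OHT were not analysed here.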
